A study of Arabidopsis thaliana with 5 samples.

How the data were processed

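Small RNA that co-precipitated with FLAG-tagged ARGONAUTE1 (AGO1, the main effector protein of plant miRNAs) was sequenced from Arabidopsis thaliana roots in the Columbia-0 background. The plants were dcl234 triple mutants, which lack the Dicer-like enzymes DCL2, DCL3 and DCL4 and keep DCL1, the enzyme that cuts miRNA precursors. In each of 5 lines the FLAG-AGO1 transgene was driven by a promoter assigned to 1 root cell layer, per the labels: pACR4 for columella, pSHR for stele, pSCR for endodermis, pCO2 for cortex and pWER for epidermis. Seedlings were grown for 6 days at 22 °C on about 5 plates per line, and RNA was extracted from anti-FLAG beads, per the labels' protocols.

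The deposited files hold, for each library, every distinct sequence of 15 to 44 nt and its read count, per the file headers. These counts are whole numbers that were not normalized. CASAVA 1.8.2 and Bowtie2 are named with the genome build TAIR10 in the submitters' processing notes, without a role, and the steps of adapter removal and length selection are not given in the sources used here. Libraries held 15522843 reads in columella, 21453974 in stele, 19595676 in endodermis, 16409688 in cortex and 25655350 in epidermis. The reads carry no molecular identifiers, so PCR copies are counted as separate reads.

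Each distinct sequence was compared with the TAIR10.1 assembly and its RefSeq annotation with bwa 0.7.19, allowing 0 mismatches and 0 gaps. A set of 67 alignments that fell on ambiguous reference bases was treated as unmatched. Reads of 18 to 26 nt were assigned to 1 annotated class in a fixed order: miRNA precursors, TAS genes, tRNA, rRNA, snRNA or snoRNA, organelles, pseudogenes, exons, and introns or intergenic sequence. The rRNA class included 300 nt upstream and 3600 nt downstream of the annotated nuclear 5.8S genes, which takes in rRNA that the annotation does not mark.

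A list of 126 sequences was fixed before the data were examined: 112 mature guide strands in 85 miRNA families, 11 passenger strands and 3 tasiRNAs (trans-acting siRNAs). All 112 guides equal a mature miRNA of the annotation. The 12 lists of families by target or regulation were fixed at the same time, with the rules of comparison and the rule for the families named in the text. That rule takes the 10 families with the highest mean level, up to 5 with the largest and 5 with the smallest ratio among those called in each layer, up to 4 members of each list by mean level, the 3 tasiRNAs, AGO1 and the TAS genes.

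A family's level was the number of reads equal to one of its guides per 1000000 reads of all listed guides, here called guide RPM. Other regions are given in RPM, reads per 1000000 of all reads of the library. Each library was compared with the geometric mean of the other 4 after a pseudocount of 1 was added to the level. A family was called higher in a layer when this ratio was at least 2, its level lay above that of every other library and its exact Poisson 95% interval overlapped none of theirs. It was called lower when the ratio was at most 0.5 under the mirrored conditions. The 41 families with a mean level of at least 10 guide RPM were compared. Each layer had 1 library, so no statistical test between layers was possible, and every call describes these libraries only. Intervals (exact Poisson for levels, Clopper-Pearson for shares, the delta method for ratios) and detection floors of 3 counts cover counting error only.

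For lists with at least 3 compared members, the median log2 ratio was placed among 10000 random lists of the same size. In these, each member was replaced by 1 of the 11 families nearest in mean level, itself included, and a family could be drawn again. A shift common to all families of a library leaves this percentile unchanged, but the pseudocount makes shifts unequal for families at low levels. The percentile was computed from guide RPM only. It was not corrected for the number of lists and layers, and the lists share members. In simulations with added noise, 2% (stele) to 16% (epidermis) of 50 random lists per layer fell outside percentiles 5 to 95. The calling rule was tested on libraries simulated from the mean profile of the 85 families at the real depths. There were 20 runs per layer and fold. Changes were simulated among the 41 compared families without the 3 highest, miR166, miR165 and miR158. A simulated 3-fold increase was recovered for 100% of the families in each of the 5 layers and a 3-fold decrease for 95% (endodermis) to 98% (stele). At 2-fold, on the threshold itself, recovery of increases ran from 40% (cortex and epidermis) to 50% (stele). No family was called without a simulated change, but these libraries had counting noise only. A shift in the share of miR165 and miR166, as between the real libraries, was not simulated, so calls that it makes were not tested.

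Alternatives covered the scaling (all reads, median-of-ratios factors, TMM factors from edgeR 4.0.16 under R 4.3.3), the filter, the pseudocount, the reference, leaving single libraries out of the reference, counting of reads that share the first 18 bases of a guide, and single mature sequences as features. A scaling without miR165 and miR166, thinning to equal depth and the analysis of promoter regions were added after the data were seen. For the promoters, 21-nt reads that match the 5000 nt upstream of the gene each promoter is named after were counted by exact sequence. AT1G62500 was taken as the CO2 gene, since the annotation gives it no such symbol. Secondary structure was predicted with RNAfold 2.7.2. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.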

Results

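Small RNAs bound to FLAG-AGO1 were profiled in 5 libraries of Arabidopsis roots, 1 for each of the columella, stele, endodermis, cortex and epidermis. The design asks which small RNAs AGO1 carries in each cell layer of a root that makes its small RNAs with DCL1 alone. Depth ran from 15522843 reads in columella to 25655350 in epidermis, with 550764 (endodermis) to 768777 (stele) distinct sequences. Between 81.1% (cortex) and 87.3% (endodermis) of the reads matched the genome without a mismatch. There were no replicates, so differences between layers could not be set against a spread between samples, and each value below comes from 1 library.

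The labels were checked first through reads from the promoter regions, which do not tell the transgene from the endogenous promoter. Reads of 21 nt that match the 5000 nt upstream of the gene each promoter is named after were concentrated in the library said to carry that promoter. The SHR region (chromosome 4, 17686687 to 17691686, upstream of SHORT-ROOT) gave 4391 reads in stele, 205 RPM (95% interval 199 to 211), and at most 9 in any other library. The WER region (chromosome 5, 4764835 to 4769834, upstream of AT5G14750, annotated as MYB66) gave 4144 reads in epidermis, 162 RPM (157 to 167), and at most 19 elsewhere. The SCR region (chromosome 3, 20064987 to 20069986) gave 496 reads in endodermis, 25.3 RPM (23.1 to 27.6), and at most 5 elsewhere. The ACR4 region (chromosome 3, 21963181 to 21968180, upstream of AT3G59420, annotated as CR4) gave 136 reads in columella, 8.76 RPM (7.35 to 10.4), and at most 1 elsewhere. Most of these own-library reads lay in part of the window, at 17689599 to 17690105 for SHR and 4768512 to 4768719 for WER. For SCR the stretch was 20068151 to 20068410 and for ACR4 21963679 to 21964390. The region upstream of AT1G62500, taken as CO2 (chromosome 1, 23126928 to 23131927), gave 11 reads in cortex and 11 in epidermis, so it did not check the cortex label.

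**Figure D1:**
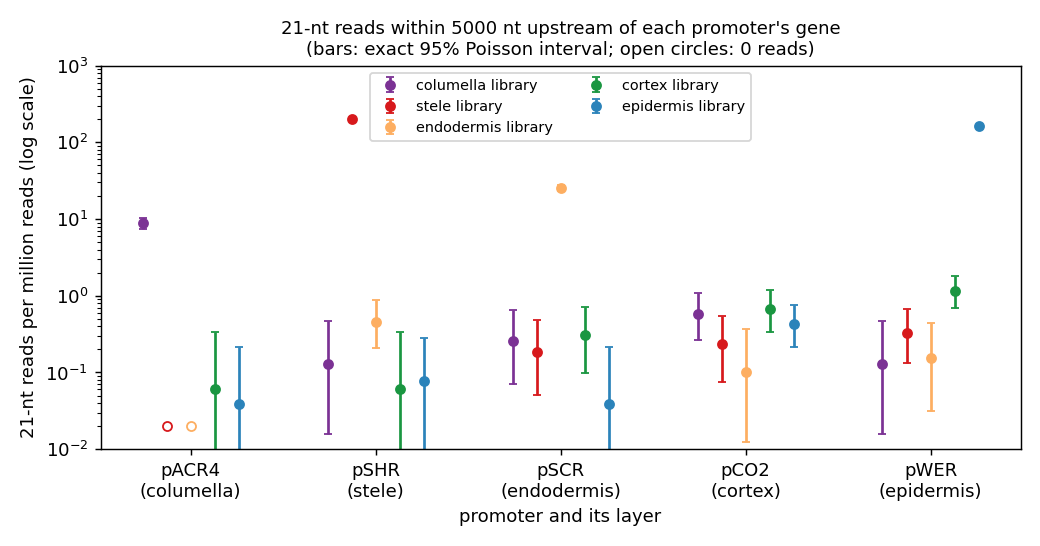
Reads of 21 nt within 5000 nt upstream of each promoter's gene (x axis), in RPM on a log scale (y axis), with 1 point per library and exact Poisson 95% intervals. Own-library levels stand at 205 for pSHR, 162 for pWER, 25.3 for pSCR and 8.76 RPM for pACR4, and those of pCO2 overlap across libraries.

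Reads of 21 nt were the largest length class in every layer. They made up 65.2% in endodermis, 56.5% in epidermis, 55.1% in stele, 51.8% in columella and 47.9% in cortex. The 95% Clopper-Pearson intervals of these shares were within 0.1 percentage points. Reads of 20 nt held 21.1% in stele and 20.4% in cortex but 11.2% in endodermis. The 24-nt class, which DCL3 makes in wild-type plants, held 1.23% (stele) to 1.83% (columella). Among 21-nt reads, 94.5% (stele) to 97.3% (endodermis) began with U, the base AGO1 prefers. Among those that were not a listed guide the share was 78.3% (columella) to 85.1% (endodermis). That set still holds variants of guides, since a 20-nt guide with an added 3′ U falls in it. In cortex 1116771 miR158 reads, not split by length, carried such a U, against 1811388 unlisted 21-nt reads. The share therefore does not describe cargo other than miRNAs. Columella held the most reads of 15 to 17 nt, 14.1% against 4.90% in stele.

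**Figure D2:**
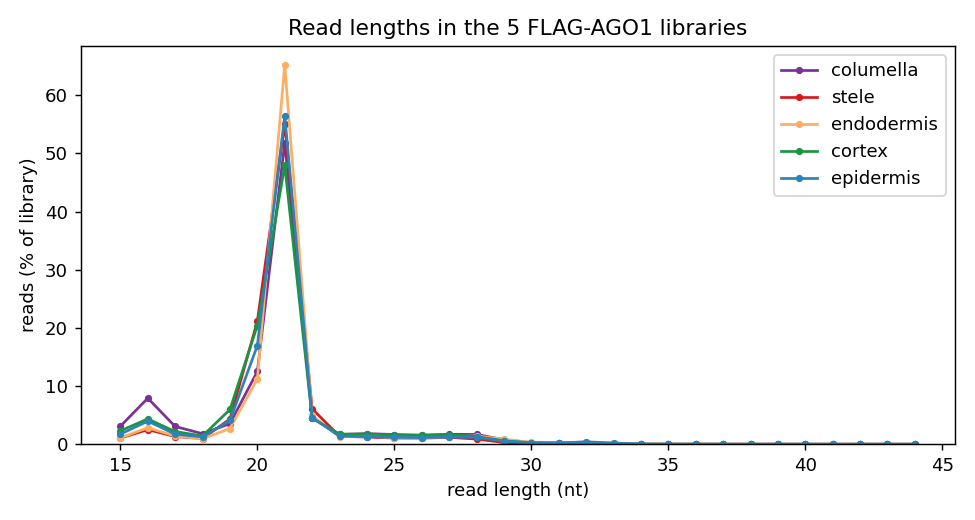
Share of reads (y axis, percent of the library) at each read length from 15 to 44 nt (x axis), with 1 line per library. All 5 lines peak at 21 nt, between 47.9% in cortex and 65.2% in endodermis, and columella shows the largest share at 15 to 17 nt.

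Annotated miRNA precursors accounted for 79.5% of reads of 18 to 26 nt in endodermis, 74.5% in epidermis, 74.4% in stele, 71.0% in columella and 69.6% in cortex. Fragments of rRNA held 9.85% in columella and 4.39% in stele, and tRNA fragments 0.795% and 0.183% in the same libraries. Reads exactly equal to a listed guide were 59.7% of all reads in endodermis, 54.6% in epidermis, 52.5% in stele, 48.9% in cortex and 48.2% in columella. The values relied on exact equality, and counting every read that shares the first 18 bases of a guide raised them to between 56.4% (columella) and 67.8% (stele).

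A few families dominated AGO1 in each layer. The miR166 and miR165 families, which target the HD-ZIP III transcription factors of root radial patterning and differ by 1 base, held 81.5% of guide reads in endodermis, 74.9% in columella, 66.8% in epidermis, 60.4% in cortex and 56.0% in stele. miR158 added 8.73% in endodermis to 23.5% in cortex. These shares count exact guides only. The family totals used to count an added U also take in guide variants. They put miR158 near miR166 in cortex (3832687 and 3997925 reads) and stele (4117809 and 4423865). miR158 stayed well below miR166 in columella (1694713 and 4552441), endodermis (1893239 and 6374201) and epidermis (4344543 and 8011338). Exact reads in cortex were 1830083 for miR158a, 58690 for miR158b and 3953813 for miR166. By mean level the next families were miR161 (30939 guide RPM), miR159 (29838), miR403 (23886), miR157 (17470), miR156 (12872), miR162 (9740) and miR846 (9439). Together the 10 highest families held 94.9% (stele) to 97.8% (columella) of guide reads. Of the 85 families, 41 passed the minimum level and 12 had 0 reads in all libraries, which at 3 counts allows up to 0.401 guide RPM in columella, the library with the fewest guide reads.

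Since miR165 and miR166 take most guide reads, a change in their share moves all other families. The median log2 ratio of the 41 families was 0.63 in stele, −0.80 in endodermis, 0.20 in cortex, −0.20 in columella and −0.03 in epidermis, and family ratios are to be read against it. Median-of-ratios factors brought these medians to between −0.05 and −0.03. No called family changed sign under any of the 4 other scalings, but many calls were lost, as given with each layer.

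In the stele library, 15 families were higher and 0 lower. miR394, which targets the F-box gene LEAF CURLING RESPONSIVENESS, reached 224 guide RPM (216 to 233) against 1.54 to 6.95 elsewhere, 53.0-fold over the other libraries (44.0 to 63.8). miR160, a regulator of auxin response factors, was 8.99-fold higher (8.22 to 9.84), at 162 guide RPM. The laccase regulator miR397 was 6.31-fold (5.63 to 7.07), miR171, which targets SCARECROW-LIKE genes, 6.19-fold (5.70 to 6.72), and the superoxide dismutase regulator miR398 5.48-fold higher (5.43 to 5.53). The other 10 were miR156, miR827, miR157, miR390, miR396, miR408, miR395, miR159, miR167 and miR472, with ratios from 4.22 (miR156) down to 2.01 (miR472). Under median-of-ratios factors the split was 8 higher and 3 lower, under TMM 5 and 5, and without miR165 and miR166 in the denominator 9 and 4. The families miR394, miR160, miR398, miR156 and miR827 kept the call under all 4 scalings.

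The guides of miR394 lie on chromosome 1 at 7058207 to 7058226 (MIR394a) and 28568821 to 28568840 (MIR394b), and share 1 sequence. Those of miR160 come from chromosome 2 (16340282 to 16340302), chromosome 4 (9888986 to 9889006) and chromosome 5 (19009158 to 19009178). All are annotated mature miRNAs within non-coding MIR genes of TAIR10.1.

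In the endodermis library, miR163 and miR165 were higher and 12 families lower. miR165 reached 276992 guide RPM against 102753 to 173905 elsewhere, 2.12-fold (2.11 to 2.12), and miR163, a 24-nt miRNA that targets methyltransferases of secondary metabolism, was 2.71-fold higher (2.68 to 2.74), at 5696 guide RPM. Both kept the call under all 4 scalings, but that of miR165 was lost when the epidermis library was left out of the reference (log2 ratio 0.96). Their loci are MIR163 (chromosome 1, 24884359 to 24884382), MIR165a (chromosome 1, 78932 to 78952) and MIR165b (chromosome 4, 369856 to 369876). miR390, which AGO7 rather than AGO1 binds to start tasiRNA production from TAS3, was 4.60-fold lower (4.45 to 4.76), at 315 guide RPM against 926 to 2911. miR161 was 3.59-fold lower (3.57 to 3.61), miR824 3.55-fold (3.21 to 3.92), miR773 3.41-fold (2.59 to 4.50) and miR823 3.12-fold lower (2.86 to 3.41). The remaining 7 were miR393, miR168, miR400, miR777, miR162, miR775 and miR403. miR390 alone kept its call under all 4 scalings, and the split of 2 higher to 12 lower became 4 to 3 with median-of-ratios factors, 8 to 1 with TMM, 2 to 6 when scaled to all reads and 7 to 1 without miR165 and miR166.

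**Figure D3:**
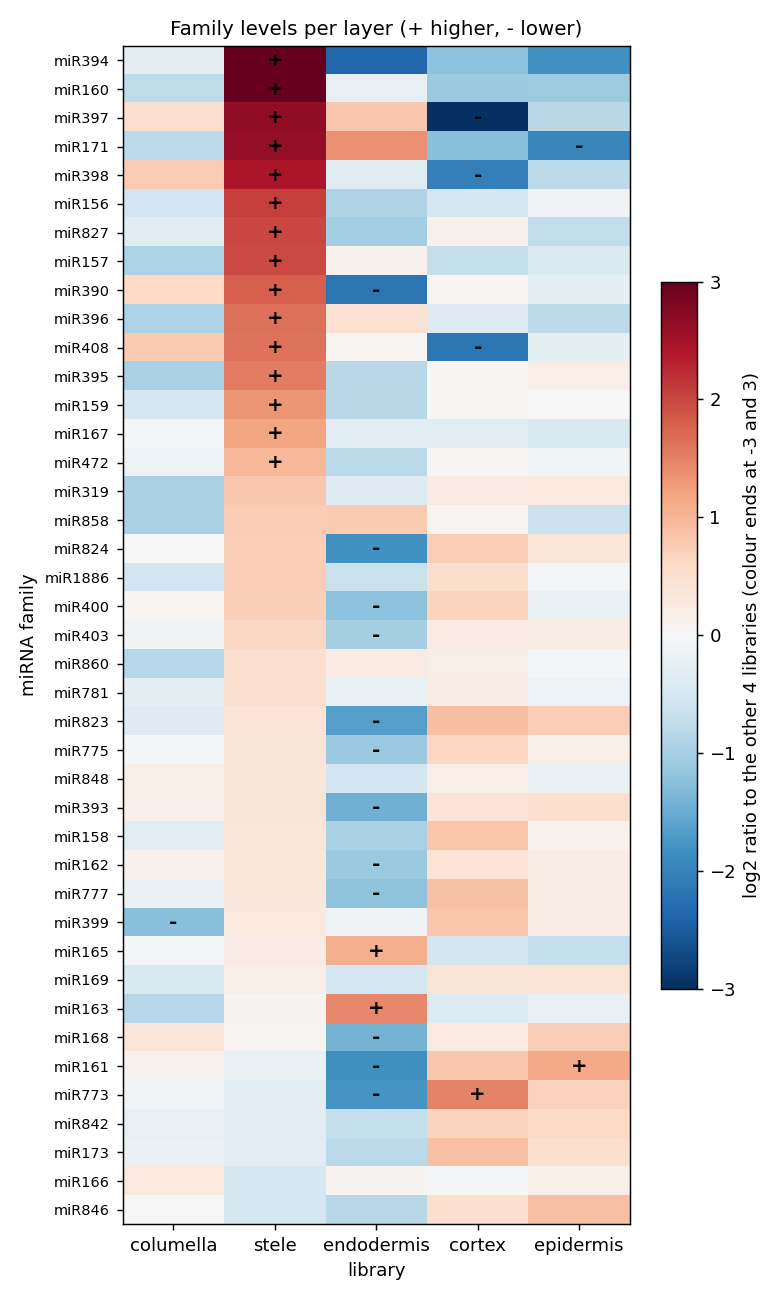
Heat map of the log2 ratio of each of the 41 families (rows) in each library (columns) to the geometric mean of the other 4, where + marks a family called higher and - one called lower. The 15 marks in stele are all + and 12 of the 14 in endodermis are -, with levels in guide RPM.

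In the cortex library the 3 measured copper-responsive families, which repress copper proteins when copper is scarce, were all lower than in every other layer. miR397 stood at 3.86 guide RPM (2.62 to 5.48) against 16.3 to 120 elsewhere, 8.78-fold lower (6.16 to 12.5). miR408 stood at 90.3 guide RPM, 4.54-fold lower (4.22 to 4.89), and miR398 at 890 guide RPM, 4.17-fold lower (4.07 to 4.27). The same 3 families were called higher in stele, where miR398 reached 10882 guide RPM, although of the 4 other scalings 3 kept the stele call of miR397 and 1 that of miR408. All 3 calls in cortex were kept under the 4 other scalings. Their loci are MIR397a and MIR397b on chromosome 4 (2625960 to 2625980 and 7878730 to 7878750), MIR398a on chromosome 2 (1041012 to 1041032), MIR398b and MIR398c on chromosome 5 (4691107 to 4691127 and 4694778 to 4694798), and MIR408 on chromosome 2 (19319933 to 19319953). miR773 was the 1 family higher in cortex, 2.79-fold (2.39 to 3.25) at 33.6 guide RPM, a call not kept when scaled to all reads or counted by prefix. Without the stele library in the reference 3 families were higher in cortex, and without the epidermis library 5.

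**Figure D4:**
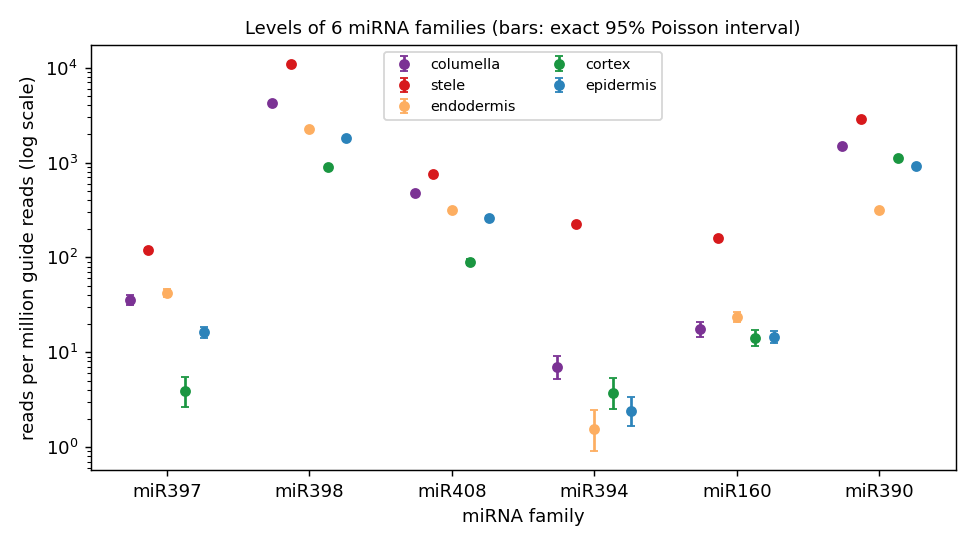
Levels of 6 families (x axis) in guide RPM on a log scale (y axis), 1 point per library with exact Poisson 95% intervals. Cortex is lowest for miR397 (3.86), miR408 (90.3) and miR398 (890), endodermis is lowest for miR390 (315), and stele is highest for all 6.

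The epidermis and columella libraries differed from the rest in few families. miR161, which targets pentatricopeptide repeat genes, was 2.21-fold higher in epidermis (2.20 to 2.21), at 50597 guide RPM, just under the threshold without miR165 and miR166 in the denominator (log2 ratio 0.996), and lost when the endodermis library was left out of the reference. miR171 was 3.92-fold lower in epidermis (3.33 to 4.61), at 11.9 guide RPM against 18.2 in cortex, and this call was kept under TMM but under none of the other 3 scalings, although the log2 ratio stayed between −2.17 and −1.85 under all 4. In columella 0 families were higher, and miR399, the phosphate-starvation miRNA, was 2.37-fold lower (2.29 to 2.46) at 405 guide RPM. That call was lost with TMM and without miR165 and miR166, and scaling to all reads gave 7 lower families in columella. Leaving the stele library out of the reference gave 3 higher families in columella, and leaving out the cortex or epidermis library gave 4 lower. In epidermis, the count without the cortex library was 4 higher and 3 lower, and without the columella library 2 lower.

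List medians move with the scaling of a library as its median does. Their percentiles are unchanged by a shift common to all families, and were computed from guide RPM only. Of the 9 nutrient-response families 6 were measured, and 5 were higher in stele (median log2 ratio 1.81, above 97.8% of random lists). In cortex 3 were lower (median −1.002, above 2.10% of random lists), and in epidermis the list stood almost as low among random lists (median −0.50, percentile 2.70) without a call. The copper subset of 3 families had medians of 2.45 in stele (percentile 97.5), 0.75 in columella (98.1), 0.05 in endodermis (88.9), −0.78 in epidermis (5.39) and −2.18 in cortex (1.07). The other listed member, miR857, had 1 read each in stele and epidermis. Among phosphate-responsive families miR399 and miR827 were measured, at 953 and 147 guide RPM in stele and 405 and 38.6 in columella. By log2 ratio, miR399 was highest in cortex (0.82, against 0.29 in stele). miR827 was lowest in endodermis (−1.02, against −0.37 in columella). miR778 had 0 reads and miR2111 a mean of 0.214 guide RPM.

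Auxin-pathway families (miR390, miR167, miR160 and miR393) were higher in stele for 3 of 4 members, with a median of 1.49 (percentile 78.6), and lower in endodermis for miR390 and miR393, with a median of −0.88 (29.98). Conserved families that target transcription factors, led by miR166, miR165, miR159 and miR157, were higher in stele for 7 of 11 members (median 1.32, percentile 80.5). Their medians were −0.24 in endodermis (93.0), −0.38 in cortex (10.1), −0.42 in epidermis (9.01) and −0.58 in columella (6.09). Of the HD-ZIP III regulators, miR165 was called higher in endodermis, and miR166 had log2 ratios between −0.51 in stele and 0.30 in columella.

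The miRNAs that regulate the small RNA machinery itself, miR168 (AGO1), miR403 (AGO2) and miR162 (DCL1), were lower in endodermis for 3 of 3 (median −1.12, percentile 10.1) and between 0.13 (columella) and 0.35 (stele) in the other layers. Under median-of-ratios factors none of those 3 was called in endodermis. Triggers of phased siRNAs (miR161, miR390, miR173, miR472, miR393 and miR400 measured) were lower in endodermis for 4 of 6, with a median of −1.35 (1.62), and had medians of 0.55 in stele (44.5) and 0.54 in cortex (87.9). In that list miR173 stood at 214 guide RPM in cortex and 83.9 in endodermis. Defence-related regulators of NLR and PPR genes (miR161, miR472 and miR400) had medians of −1.24 in endodermis (6.99), 0.72 in stele (66.8) and 0.66 in cortex (87.4), and miR825 averaged 0.253 guide RPM.

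Among all list percentiles, which were not corrected for their number, that of young Brassicaceae families in cortex was the most extreme. Their 15 measured members of 53, among them miR158, miR161, miR846 and miR163, had a median of 0.66 there, above 99.5% of random lists, although miR773 was the 1 member called higher. In endodermis 7 of the 15 were lower (median −0.96, percentile 8.50). Families with 22-nt guides (5 of 13 measured, led by miR472, miR173, miR393 and miR777) had medians from −0.81 in endodermis (29.0) to 0.41 in cortex (69.9). miR390, listed as cargo of another Argonaute, was present at 315 (endodermis) to 2911 (stele) guide RPM.

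Across the 41 families, libraries were compared in pairs. Cortex and epidermis were nearest, with a Pearson r of log2 level of 0.993 (Spearman rho 0.988) and a standard deviation of the log2 differences of 0.53. By the same measures stele and cortex were farthest, with an r of 0.935 (rho 0.876) and a standard deviation of 1.57. By the number of families at least 2-fold apart, stele and endodermis were farthest, with 28 against 15 for stele and cortex. This count moves with a common offset between libraries, and the median log2 ratios of stele and endodermis were 0.63 and −0.80. Median-of-ratios factors, which brought both medians to −0.03, were not applied to it. These values are across families, which are not independent replicates, for 10 pairs of libraries.

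DCL4, which normally makes tasiRNAs, was absent, and tasiRNA loci still gave 21-nt reads. Counts were added over 7 TAS genes, so a read that matches more than 1 of them counts for each. The sums were 389 RPM in columella (379 to 399), 565 in endodermis (554 to 575), 695 in cortex (682 to 708), 712 in epidermis (702 to 722) and 771 in stele (760 to 783). Between 52.1% (stele) and 55.9% (epidermis) lay on the antisense strand. TAS3b differed from this, with 0% antisense in columella, stele and endodermis, 0.962% in cortex and 2.83% in epidermis, from 73 (endodermis) to 112 (stele) reads. It gave 0 reads of 22 nt in each library. TAS1C (AT2G39675) led with 194 (columella) to 352 (stele) RPM, TAS2 gave 59.7 to 175, TAS3 75.2 to 158, TAS1A 47.7 to 95.3, TAS1B 5.93 to 9.67 and TAS3b 3.73 to 6.34, and the gene annotated as TASIR-ARF had 1 read in all. Of the 3 listed tasiRNAs, tasiR-ARF 5D7 (TTCTTGACCTTGTAAGACCCC) was found at 7.32 RPM in stele (6.22 to 8.56) and 2.86 to 4.87 elsewhere. siR255 (TTCTAAGTCCAACATAGCGTA) had 1 read in endodermis, 3 in cortex and 6 to 13 in the others, and 5D8 had 0 reads in each library, which allows up to 0.193 RPM in columella.

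AGO1 itself (AT1G48410, chromosome 1, 17885633 to 17892632) gave 21-nt reads at 183 RPM in stele (177 to 189), 24.01 in epidermis (22.2 to 25.98), 21.5 in endodermis (19.5 to 23.7), 11.7 in columella (10.1 to 13.6) and 9.45 in cortex (8.02 to 11.1). Between 54.7% (stele) and 61.6% (endodermis) of them were antisense, and 94.8% (cortex) to 99.7% (epidermis) lay in exons, which cover 52% of the gene. Reads from the endogenous gene and from the FLAG-AGO1 transgene cannot be separated by sequence.

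Listed passenger strands, at most 1 per family, were rare for abundant families. The list does not cover every passenger of a family. The listed passenger of miR156 had 0 reads in each library, while the unlisted miR156b-3p reached 403 guide RPM in stele. All listed passengers together held 170 guide RPM there. For miR157 they were 0.192% (endodermis) to 0.346% (columella) of guide plus passenger reads, and for miR396 0.138% (cortex) to 0.355% (columella). The passenger of MIR393b held from 17.6% in cortex (13.8 to 22.1) to 32.9% in columella (28.0 to 38.2) of guide plus passenger reads of miR393. For miR171 the share ran from 0.417% in endodermis (0.114 to 1.06, 4 passenger reads) to 18.9% in columella (14.0 to 24.7, 42 reads). It sets 1 listed passenger against the guides of all miR171 members. In endodermis the unlisted miR171b-5p and miR171c-5p stood at 8.89 and 5.04 guide RPM, against 0.342 for the listed passenger. In columella these were 4.41, 3.74 and 5.61, so the range does not describe all miR171 passengers.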

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

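The tests on promoter reads and on scaling were chosen after their results had been seen, while those on depth and on GC content were chosen after the data had been seen but before their own results were. The criterion for scaling in the second pattern was also changed after its results had been seen. A first form counted calls kept under each of 4 scalings (5 of 15 in stele, 1 of 12 in endodermis), and would have put both sets with the share of miR165 and miR166. A later form counted calls under the scaling that leaves these families out, and the last form in addition takes no support from a shift that is nearly common to all families. No sample group held enough libraries to look for outlying samples.

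Signals outside the miRNA list were flagged because they stood above what a count of 0 allows. They were the 21-nt reads upstream of SHR in stele (205 RPM), of WER in epidermis (162), of SCR in endodermis (25.3) and of ACR4 in columella (8.76). Others were 21-nt reads on AGO1 in stele (183 RPM) and at a locus without annotation on chromosome 5 in stele (2622 RPM). Among annotated mature miRNAs that the list left out, miR869.2 reached 2705 guide RPM in stele against 248 to 384 elsewhere, and miR5012 reached 237 in cortex, 212 in epidermis and 140 in columella but 14.7 in stele and 10.1 in endodermis.

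The first pattern is that 21-nt reads upstream of 4 promoter genes lay in the library that carries the promoter. Breakdown of transcripts is argued against, because the 21-nt share in each window was at least 5.68 times that of rRNA reads in the same library, and the weaker strand held 32.6% to 46.0% of the reads. The cortex library showed no excess over every other library, as its CO2 window gave 0.670 RPM, within the intervals of columella and epidermis. An exchange with the library of another promoter is argued against, because the 4 other windows reached at most 1.20% of their own-library level in cortex. A cortex library from a line with none of the 5 promoters cannot be told apart from a CO2 promoter that gives few such reads, or from a window at the wrong gene, since AT1G62500 was taken as CO2 without a symbol in the annotation. As a hypothesis, the transgenes may themselves give rise to DCL1-dependent 21-nt siRNAs that AGO1 binds. This was not tested. The 5 libraries ranked alike by 21-nt reads on AGO1 and by their own promoter reads, although the levels were not in proportion. On AGO1 these were 183 RPM in stele, 24.01 in epidermis, 21.5 in endodermis, 11.7 in columella and 9.45 in cortex. The AGO1 intervals of epidermis and endodermis overlapped, as did those of columella and cortex, so the order within these pairs is not resolved. The cortex promoter level was also no excess over other libraries, and the ranking does not test the hypothesis.

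The second pattern is the 15 families higher in stele and the 12 lower in endodermis. When every library was thinned to the guide reads of the smallest, 26 of these 27 calls were kept. Thinning leaves the expected ratios unchanged. It therefore shows only that these calls do not rest on unequal counting error, and cannot decide on other effects that go with depth. Leaving miR165 and miR166 out of the denominator moved the log2 ratios of the 12 by 0.74 to 0.91 in endodermis and of the 15 by −0.66 to −0.36 in stele. A shift this similar between families ends most calls smaller than itself plus the threshold, whatever the cause. In endodermis 1 of 12 calls was kept. The log2 ratios of 10 others then lay between −0.94 and −0.10, and that of miR773 went from −1.77 to −1.03, with an interval that overlapped another library's. In stele 8 of 15 were kept and 5 fell to log2 ratios of 0.35 to 0.97, while miR171 (2.63 before, 2.02 after) and miR396 (1.66 and 1.01) stayed at least 2-fold higher but lay below endodermis. In both layers the share of these families cannot be told apart from a change of the others as the source of the calls not kept. Levels relative to the sum of guides cannot show whether miR165 rose in endodermis or the other families fell, and a difference between the layers stays open.

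The third pattern is the low level of miR397, miR398 and miR408 in cortex. Scaling is argued against, since the highest log2 ratio of the 3 under 4 other scalings was −2.19, as is GC content, since it was −2.02 after a linear trend over the other 38 families was removed. With 1 library of the cortex line, a difference in plates or copper supply cannot be told apart from a difference between the layers, which may also be biological.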

How the results depend on the processing

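The scaling without miR165 and miR166 and the thinning to equal depth were chosen after the data had been seen, as were the promoter counts from reads with 1 genome match, which stayed within their counting intervals in each promoter's own library. In the SCR window such reads fell from 4 to 2 in columella, 4 to 1 in stele, 5 to 2 in cortex and 1 to 0 in epidermis. No paired analysis was possible because each layer had 1 library and the values come from no test. No family's log2 ratio among the 36 calls changed sign under any setting that compares families. Of single sequences with a mean level of at least 10 guide RPM in these calls, 2 of 46 had the opposite sign, miR159c (−1.57) and miR395a-d-e (−0.099) in stele. Among all 57 the number was 5, with miR167d (−0.13) and miR171a (−1.46) in stele and miR171a in epidermis (0.18). Causes of shifts were not tested unless named.

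Counts of called families moved with the scaling. Scaling to all reads gave 7 lower in columella, 6 lower in endodermis, 0 higher in cortex and 0 lower in epidermis. Median-of-ratios factors gave 8 higher and 3 lower in stele, 4 higher and 3 lower in endodermis, and 0 lower in epidermis. TMM factors gave 0 lower in columella, 5 higher and 5 lower in stele, and 8 higher and 1 lower in endodermis. Without miR165 and miR166 there were 2 higher and 0 lower in columella, 9 higher and 4 lower in stele, 7 higher and 1 lower in endodermis, 5 lower in cortex, and 0 higher and 0 lower in epidermis.

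With no filter, 2 families were higher in columella, and a minimum of 100 left 0 higher in cortex and 0 lower in epidermis, as fewer families were compared. The median reference gave 0 higher in epidermis. Prefix counting gave 0 higher in cortex and 0 lower in epidermis. Single sequences gave 1 higher and 4 lower in columella and 0 lower in epidermis. Thinning gave 0 lower in epidermis. A pseudocount of 0.1 kept each count within 1.5 times.

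Leaving 1 library out of the reference gave 0 to 3 higher (3 without stele) and 1 to 4 lower in columella (3 without endodermis, 4 without cortex or epidermis). It gave 1 (without epidermis) to 4 (without stele) higher in endodermis, 1 to 5 higher in cortex (3 without stele, 5 without epidermis), and in epidermis 0 (without endodermis) to 4 (without cortex) higher and 1 to 3 lower (2 without columella, 3 without cortex). In stele the counts stayed at 15 and 0.

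Guide shares in columella, stele, endodermis, cortex and epidermis were 56.4%, 67.8%, 67.7%, 64.0% and 67.3% with prefix counting, 69.9%, 63.6%, 72.9%, 67.1% and 69.8% of reads of 20 to 22 nt, and 56.7%, 63.0%, 68.4%, 60.4% and 65.4% of genome-matched reads. In the same order, 21-nt shares were 12.6%, 25.1%, 16.01%, 14.0% and 16.5% of distinct sequences, 19.4%, 29.7%, 28.5%, 21.6% and 24.6% of reads that were not a listed guide, and 54.8%, 58.3%, 68.4%, 51.4% and 60.0% of genome-matched reads. Without listed guides, 78.3%, 80.2%, 85.1%, 81.9% and 82.5% of 21-nt reads began with U, among reads that still include tailed guides. Depth limits families near 10 guide RPM, where columella held 7483816 guide reads and epidermis 14006478.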

Other observations

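Members of 1 family could differ in direction between layers, as described here from single mature sequences chosen after their values were seen. miR171b and miR171c reached 164.7 guide RPM in stele and 81.7 in endodermis against 10.2 to 19.2 in the other layers. miR171a, by contrast, stood at 0.0888 in stele and 0.0855 in endodermis, 1 read each, and at 1.71 to 4.81 elsewhere. Among the 68 sequences with a mean level of at least 2 guide RPM, 4 were at least 2-fold lower in both stele and endodermis than in each of the other 3 libraries: miR158b, miR159c, miR171a and miR822. Another 2, miR171b-c and miR397a, were at least 2-fold higher in that pair. Of the other 9 pairs of libraries, cortex with epidermis had 2 such sequences, miR167a-b and miR397b, both lower, and the remaining 8 pairs had 0. miR159c stood at 23.9 in endodermis and 30.1 in stele against 129 to 149 elsewhere. These differences are counting results from 1 library per layer.

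The locus without annotation and the rule that picks it were chosen after its values were seen: of the clusters of intergenic 21-nt reads with at least 10 sequences, it has the most reads. It lies on the minus strand of chromosome 5, 22322719 to 22322906 in TAIR10.1, and overlaps 0 annotated genes. Its 21-nt reads stood at 2622 RPM in stele (2601 to 2644), 798 in endodermis, 507 in epidermis, 478 in cortex and 353 in columella, and 99.5% to 99.7% of its reads of 18 to 26 nt came from the minus strand. The 188 nt fold into a structure of −137.6 kcal/mol in which 89.4% of bases are paired, against −58.2 kcal/mol for the lowest of 100 shuffled sequences.

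Non-templated U at the 3′ end, a mark of uridylated miRNAs, was frequent in miR158, at 28.9% (columella) to 31.5% (stele) of its reads. It reached 14.3% (stele) to 23.005% (cortex) in miR319 and 5.53% (cortex) to 9.08% (endodermis) in miR156, but at most 0.208% in miR157. In miR166, the only other family in which such tails were counted, it held 0.0618% (columella) to 0.185% (stele). The ranges of miR158, miR319 and miR156 over the layers did not overlap, while those of miR157 and miR166 did.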
